A study of Mus musculus with 24 samples.

How the data were processed

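PolyA RNA was sequenced from mouse OTX2-dTAG-EGFP cells on a hybrid BL6/129 background, harvested with Accutase and extracted with Trizol, per the labels. Epiblast stem cells (EPI) were kept in activin A at 20 ng/ml, FGF2 at 12.5 ng/ml and NVP at 175 nM. Primitive streak cells (PS) were made in 16 h with activin A at 40 ng/ml and CHIR at 3 µM, an activator of WNT signalling. Definitive endoderm was made with activin A at 100 ng/ml and LDN, a BMP receptor inhibitor, at 100 nM for 24 h (DE1) or 48 h (DE2). dTAG13 or DMSO was present for 21 h per the labels. Which addition belongs to which harvest is an inference, and 21 h is longer than the 16 h of PS induction, so part of the PS exposure may lie in the preceding culture. The 8 groups of stage and treatment hold 3 libraries each, 1 per cell line (7H, 7H1 and 7H2). How the lines are related is not given in the sources used here, so p-values speak for these 3 lines alone. In the fit reported they rest on the spread between libraries within groups, pooled over the 8 groups. That fit ignores the pairing by line, so its p-values do not measure how the dTAG13 effect varies between lines.

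The deposited signal is a table of normalised read counts for 18205 genes, made by the authors with the build mm10 and DESeq2 named in the submitters' processing notes without versions. The aligner, the counting tool and the strand setting are not given in the sources used here. Without the strand, reads of a gene and of an antisense partner, Otx2 included, cannot be told apart. Every value column was used. Of the gene IDs, 18116 matched the mouse annotation used here (GRCm38, GENCODE M21), which gives the coordinates. Names were missing for 71 IDs, of which 1 was filled from the annotation and 70 stayed unnamed, 23 names that had been turned into dates were restored by ID, and 20 names were shared by IDs.

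Totals were 24.42 to 27.25 M per library. The smallest step between low values gave what 1 read is worth and from it an estimated depth of 17.2 to 33.9 M reads. Of values under 6, 58.4 to 72% lay within 0.1 of a whole number of reads, too few for whole reads to be recovered, so no count model was used. The 10 highest genes took 4.76 to 6.29% of a library and mitochondrial genes 1.34 to 2.52%. Pearson's r between libraries on the log scale was 0.9528 to 0.9705 within groups, and 0.9719 for the most similar pair of any groups.

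Values were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an intensity trend and robust empirical Bayes. The fit held all 24 libraries and the 8 groups, with 16 residual degrees of freedom and a median of 21 in all. Genes with at least 10 in at least 3 libraries were tested, 15037 in all, and called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. The comparisons were dTAG13 minus DMSO at each of the 4 stages, successive stages in DMSO, and differences of the dTAG13 effect between successive stages. The dTAG13 comparisons share no library, while successive stage comparisons share the middle stage. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

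The replicate number is the cell line, so it pairs samples across treatments. Deviations from the group means correlated at 0.0703 to 0.381 between libraries of the same line, and in all 12 cases the own line was the highest. The fit without the line as a block is the one reported, and the block is an alternative. For the dTAG13 comparisons, the lists and the differences of effects, the block is a separate line term within each stage. For the steps between stages it is a line term common to all stages.

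Fixed lists, 33 of pathways, stages and other cell types, were tested at 4 stages (132 tests adjusted together) by camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, and fry asks whether the members move one way. Differentiation sets were the 200 highest and 200 lowest moderated statistics of a vehicle step sharing no library with the stage tested, 8 tests in all. Overlaps of calls were tested with Fisher's exact test, 12 tests in all.

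Samples, comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, except 1 alternative, the setting without genes that have a 0 beside 50 or more. Named genes were Otx2, the 10 largest rises and falls per dTAG13 comparison (8 per stage step, 5 per difference of effects) among called genes with a mean of at least 50, one sign in all 3 lines and a non-predicted symbol, and the 4 members of each list with the smallest p. The rule allowed genes to be left out for space, and a few further genes are not reported here. Which genes were left out was decided after their values were seen, and genes without exact zeros and called genes were favoured, so the named genes are not an unbiased draw and counts of their stability cover these genes alone.

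The limma step was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 71 and 95% in EPI (14845 genes in the test), 66 and 90% in PS (14831), 71 and 92% in DE1 (14846) and 64 and 90% in DE2 (14847). The share of false calls was 6.21, 2.5, 6.86 and 7.23%, so in EPI, DE1 and DE2 it lay above what the threshold of 0.05 aims at. The simulated libraries were drawn independently, without effects of the line, and the changed genes had a DMSO mean of at least 50. The real libraries deviate together by line, so these rates do not carry over to them or to low genes. Alternatives were other pseudocounts, filters and scalings, the block, the compared libraries alone, a 2-fold rule, and each library and line left out.

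An exact 0 may be a low count or a failed estimate. Of the genes tested, 272 (1.81%) had a library at 0 beside one of at least 50 in the same group. Genes with zeros in the compared groups are given per library.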

Results

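Gene expression was measured by polyA RNA sequencing in 24 libraries of mouse cells carrying OTX2-dTAG-EGFP. OTX2 is a homeobox transcription factor of the epiblast and the anterior embryo. A dTAG fusion is destroyed by the proteasome when the degrader dTAG13 is added, and DMSO was the vehicle. The cells were epiblast stem cells (EPI), primitive streak stage cells (PS), and definitive endoderm at 24 h (DE1) and 48 h (DE2) from PS. Each stage had 3 libraries with dTAG13 and 3 with DMSO, 1 from each of the lines 7H, 7H1 and 7H2. The stated purpose was to find genes that depend on OTX2 at each stage. Deposited values per library, in M (mega), summed to 24.42 to 27.25 M, and the steps of the low values put the depth at an estimated 17.2 to 33.9 M reads. Between 15260 and 16536 genes lay above 0 in a library. Values are normalised read counts, given as mean ± SD with n = 3, and log2 fold changes are those of the value plus 1, which understates the change of low genes. Genes are called from adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment.

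The first 3 principal components, with 36.2, 15.6 and 8.75% of the variance, separated the stages. The fourth (6.61%) separated the treatments except in EPI. PS scored -1.91 to 1.29 with dTAG13 and 7.98 to 11.1 with DMSO. DE1 scored -28.4 to -24.6 and 21 to 32.8, and DE2 -72.4 to -42.9 and 44.6 to 61.8. In EPI scores overlapped, with dTAG13 lower in each line.

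**Figure D1:**
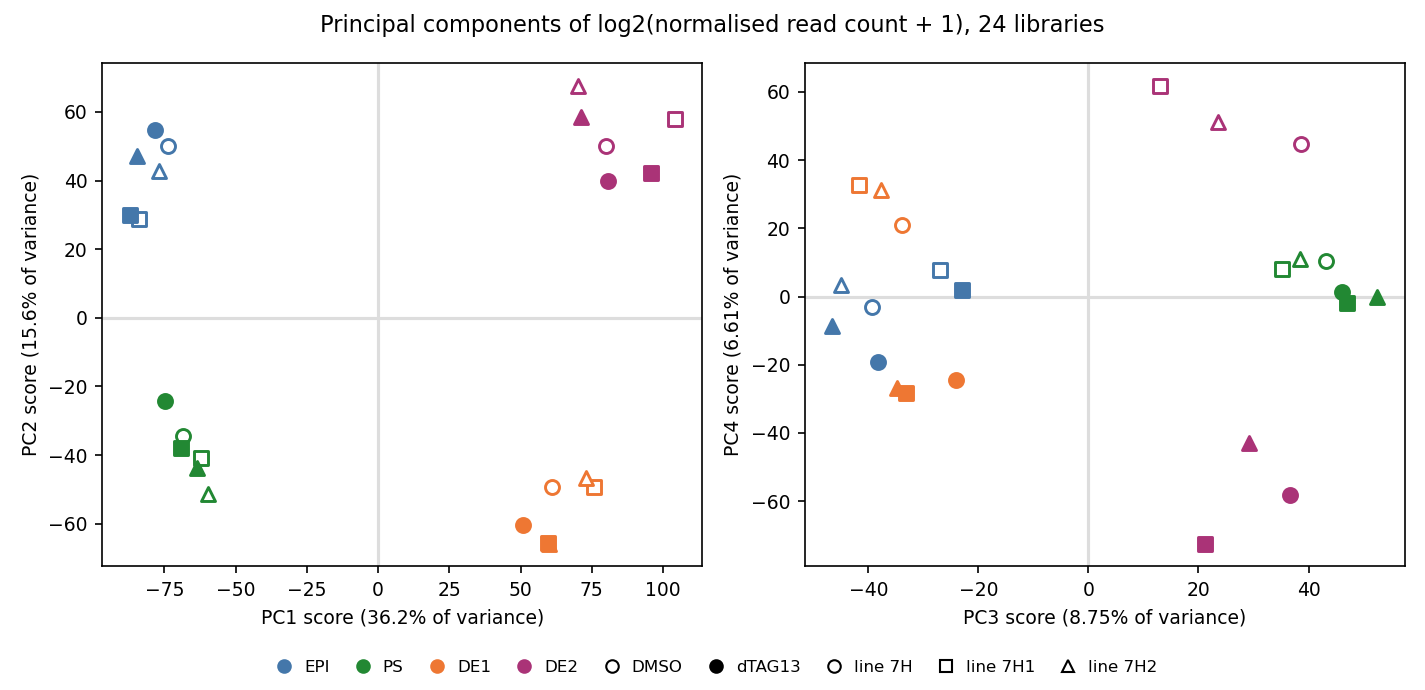
Scores of the 24 libraries on principal components 1 and 2 (left) and 3 and 4 (right), with the share of variance on each axis; colour gives the stage, filled symbols dTAG13, open symbols DMSO and symbol shape the cell line. DE2 lies at -72.4 to -42.9 (dTAG13) and 44.6 to 61.8 (DMSO) on component 4.

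The Otx2 transcript (chromosome 14, 48657677 to 48673819, minus strand) was measured in every library, which does not check depletion, since dTAG13 acts on the protein. In EPI it stood at 1693, 1476 and 1817 with DMSO and at 2352, 2302 and 2949 with dTAG13 in lines 7H, 7H1 and 7H2. In PS it stood at 2342, 3248 and 3699 and at 1708, 2497 and 3268. In DE1 the values were 8656, 10972 and 10215 and 12024, 13704 and 13790, and in DE2 8625, 12385 and 9470.5 and 10553, 13640 and 13218. Otx2 was not called in any stage, at adjusted p = 0.73, 0.702, 0.253 and 0.336. With the cell line as a block the adjusted p was 0.00222, 0.0377, 0.00256 and 0.0104, with log2 fold changes of 0.60, -0.34, 0.41 and 0.30.

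The vehicle libraries were compared first between successive stages, to describe the conversion itself. From EPI to PS, every tested member of the primitive streak list rose, and 8 of 19 members of the epiblast list fell while 3 rose. Mixl1, a homeobox gene of the mesendoderm (chromosome 1, 180693043 to 180697034), rose from 125 ± 78.9 to 14611 ± 553 (log2 fold change 7.05, SE 0.52, adjusted p = 2.22e-08). Lhx1, a LIM homeobox gene of the anterior streak (chromosome 11, 84518284 to 84525535), rose from 718 ± 143 to 22615 ± 3663 (log2 fold change 4.98, SE 0.34, adjusted p = 4.96e-09). Utf1, a chromatin factor of pluripotent cells (chromosome 7, 139943789 to 139945112), fell from 10981 ± 2506 to 1041 ± 127 (log2 fold change -3.38, SE 0.39, adjusted p = 4.71e-06). In this step 2200 genes rose and 1932 fell, of 15037 tested, and of these 686 rose and 960 fell at least 2-fold.

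In the primitive streak list 21 of 21 members rose, 0 fell and 0 were not called (21 rose and 0 fell when adjusted over the list alone). Other members were Evx1 (log2 fold change 8.29), Sp5 (6.23) and Gsc (4.77). Mesp1, a factor of nascent mesoderm, stood at 0, 0.896 and 0.982 in EPI and at 1102, 1995 and 2971 in PS. In the definitive endoderm list 13 of 24 members rose, 1 fell and 10 were not called (14 rose and 1 fell when adjusted over the list alone), with Gata6 from 122 ± 27.6 to 4055 ± 697 and Gata4 from 65.8 ± 32.7 to 1105 ± 381. In the anterior endoderm list 10 of 19 members rose, 1 fell and 8 were not called (10 rose and 1 fell when adjusted over the list alone), with the WNT antagonist Frzb from 94.2 ± 44.8 to 2735 ± 583 and the retinoic acid degrading enzyme Cyp26a1 from 585 ± 57.7 to 8434 ± 2394. In the mesoderm list 16 of 27 members rose, 2 fell and 9 were not called (16 rose and 2 fell when adjusted over the list alone), with the NOTCH ligand Dll1 from 27 ± 10.8 to 652 ± 86.8. In the posterior endoderm list 9 of 15 members rose, 0 fell and 6 were not called (9 rose and 0 fell when adjusted over the list alone). Of the HOX list, 1 of 20 members rose, 0 fell and 19 were not called (1 rose and 0 fell when adjusted over the list alone), and the member that rose was Hoxb1, from 4.32 ± 1.93 to 196 ± 55.6. In the epiblast list 3 of 19 members rose, 8 fell and 8 were not called (3 rose and 8 fell when adjusted over the list alone). Sox3 fell from 1348 ± 452 to 92.3 ± 43.1, and the epithelial cadherin Cdh1 fell from 19414 ± 1116 to 12265 ± 1127. Enpp3 (log2 fold change -4.06), Tmem154 (-4.49) and Vstm2l (-4.91) were among the largest falls. Rescaling to equal totals gave 1693 rises and 2360 falls, and without line 7H2 1349 genes were called in all.

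From PS to DE1, 19 of 24 members of the definitive endoderm list rose, and 14 of 21 members of the streak list fell while 5 rose. Cxcr4, a chemokine receptor of definitive endoderm (chromosome 1, 128588199 to 128592293), rose from 814 ± 469 to 9422 ± 898 (log2 fold change 3.72, SE 0.36, adjusted p = 9.81e-08). Shisa2, an inhibitor of WNT and FGF receptor maturation (chromosome 14, 59625308 to 59631660), rose from 319.7 ± 116 to 10676 ± 1411 (log2 fold change 5.11, SE 0.22, adjusted p = 7.58e-13). Pou5f1, the pluripotency factor OCT4 (chromosome 17, 35506018 to 35510772), fell from 27613 ± 3848 to 1139 ± 253 (log2 fold change -4.61, SE 0.56, adjusted p = 3.93e-06). In this step 3263 genes rose and 3370 fell, of these 1710 and 1455 at least 2-fold.

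In the definitive endoderm list 19 of 24 members rose, 0 fell and 5 were not called (20 rose and 0 fell when adjusted over the list alone). Prdm1 rose from 389.9 ± 112 to 3409 ± 353 and Hhex from 941 ± 286 to 5924 ± 392. In the anterior endoderm list 9 of 19 members rose, 2 fell and 8 were not called (10 rose and 2 fell when adjusted over the list alone), among them the secreted frizzled-related genes Sfrp5 from 8.4 ± 3.85 to 1045 ± 624 and Sfrp1 from 1555 ± 571 to 33466 ± 2533. The NODAL antagonist Lefty2 rose from 1637 ± 534 to 16499 ± 2687, the pepsinogen gene Pga5 from 132 ± 56.6 to 29197 ± 3133 and the muscle transcriptional coactivator Myocd from 4.08 ± 4.83 to 708 ± 132. The calcium-sensing receptor Casr was at 1.39, 0 and 3.01 in PS and 392, 657 and 720.3 in DE1, and the serotonin transporter Slc6a4 at 6.11, 0 and 1.76 and 437, 517 and 576. Rap1gap2 was listed at 0 in all 3 PS libraries and stood at 428, 217 and 339.5 in DE1. In the primitive streak list 5 of 21 members rose, 14 fell and 2 were not called (5 rose and 14 fell when adjusted over the list alone), with Evx1 from 3745 ± 188 to 71.3 ± 34.4, the ligand Apln from 5486 ± 908 to 23.8 ± 11.8, Wnt3 from 2935 ± 134 to 391 ± 26.3 and Mesp1 from 2022 ± 935 to 47 ± 29.6. In the posterior endoderm list 2 of 15 members rose, 11 fell and 2 were not called (2 rose and 12 fell when adjusted over the list alone), with Wnt5b from 1258 ± 75 to 46.8 ± 10.7. In the mesoderm list 7 of 27 members rose, 13 fell and 7 were not called (7 rose and 13 fell when adjusted over the list alone), in the HOX list 0 of 20 members rose, 8 fell and 12 were not called (0 rose and 8 fell when adjusted over the list alone), and in the epiblast list 7 of 19 members rose, 9 fell and 3 were not called (7 rose and 9 fell when adjusted over the list alone). Tnfrsf19 fell from 1534 ± 242 to 10.1 ± 5.82. Hoxb1 went from 251, 198 and 139.8 to 0, 4.18 and 0, Nkx1-2 from 1069.8, 565 and 528 to 2.25, 0 and 3.29 and Sp8 from 669.6, 344 and 282 to 12.4, 0 and 0.

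From DE1 to DE2, 8 of 19 members of the anterior endoderm list rose, and 10 of 21 members of the streak list fell. Isl1, a LIM homeobox gene of foregut and other progenitors (chromosome 13, 116298281 to 116309689), rose from 49 ± 18.7 to 1673 ± 428 (log2 fold change 5.11, SE 0.61, adjusted p = 1.66e-06). Cdh1 (chromosome 8, 106603351 to 106670246) rose from 18283 ± 1162 to 43351 ± 1746 (log2 fold change 1.25, SE 0.08, adjusted p = 4.24e-10). Sp5, a WNT target (chromosome 2, 70474923 to 70477729), fell from 653 ± 33.6 to 23.7 ± 13.4 (log2 fold change -4.92, SE 0.50, adjusted p = 3.68e-07). In this step 3039 genes rose and 2875 fell, of these 1649 and 774 at least 2-fold. Quantile normalisation moved the median of all genes by -0.105 (log2) here and turned the balance to 2629 rises and 3471 falls.

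In the anterior endoderm list 8 of 19 members rose, 2 fell and 9 were not called (10 rose and 2 fell when adjusted over the list alone). Prox1 rose from 209 ± 28.3 to 604 ± 241, and Frzb fell from 5215 ± 586 to 789 ± 473. The gut peptide genes Sst and Pyy stood at 0, 0 and 2.38 and 0.933, 0 and 0 in DE1, and at 225, 250.2 and 874 and 99.3, 401 and 243 in DE2. In the definitive endoderm list 7 of 24 members rose, 3 fell and 14 were not called (7 rose and 4 fell when adjusted over the list alone), with the keratins Krt19 from 1126 ± 91.9 to 10066 ± 1559.5 and Krt18 from 17395 ± 579 to 49849 ± 3544. Tmem178 rose from 11.9 ± 8.14 to 1843 ± 150. Cdh8, a type II cadherin, stood at 1.63, 0 and 0 in DE1 and 524, 629 and 806 in DE2, and Best2 was listed at 0 in all 3 DE1 libraries and stood at 239.7, 563 and 361 in DE2. In the primitive streak list 0 of 21 members rose, 10 fell and 11 were not called (0 rose and 10 fell when adjusted over the list alone), with Mixl1 from 2894 ± 200.1 to 86.7 ± 71.5, Fgf8 from 10090 ± 485 to 2068 ± 429 and the growth factor receptor Pdgfra from 5053 ± 466 to 338 ± 103. In the mesoderm list 5 of 27 members rose, 9 fell and 13 were not called (5 rose and 9 fell when adjusted over the list alone), in the posterior endoderm list 5 of 15 members rose, 2 fell and 8 were not called (5 rose and 2 fell when adjusted over the list alone), and in the HOX list 4 of 20 members rose, 0 fell and 16 were not called (4 rose and 0 fell when adjusted over the list alone). In the epiblast list 7 of 19 members rose, 6 fell and 6 were not called (7 rose and 7 fell when adjusted over the list alone), with Zic2 from 4608 ± 195 to 984 ± 264. Vax1 (log2 fold change -5.73) and Gfi1 (-4.31) fell too. Without line 7H2 the calls of Krt19, Krt18 and Fgf8 were lost, and the count was 4077, against 3915 without 7H1.

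**Figure D2:**
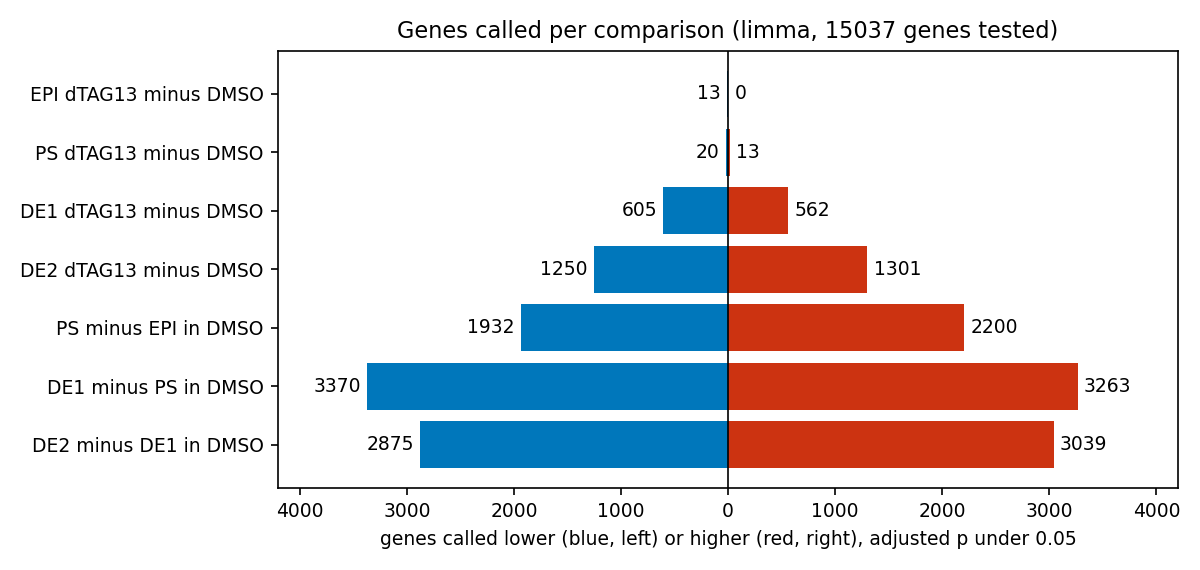
Genes called higher (red, right) and lower (blue, left) in the 4 dTAG13 minus DMSO comparisons and the 3 stage steps in DMSO, at adjusted p under 0.05 among 15037 tested. The dTAG13 counts were 13 in EPI, 33 in PS, 1167 in DE1 and 2551 in DE2. Fitted alone, DE1 called more than DE2 (2304 and 1564).

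In EPI, genes of anterior and endodermal fate were among those lowered by dTAG13. Dkk1, a secreted WNT antagonist (chromosome 19, 30545863 to 30549665), fell from 154 ± 17.6 to 10.6 ± 9.92 (log2 fold change -4.11, SE 0.52, adjusted p = 0.0016). Sox17, the SRY-box factor of definitive endoderm (chromosome 1, 4490931 to 4497354), fell from 161 ± 37.9 to 15.7 ± 6.92 (log2 fold change -3.32, SE 0.50, adjusted p = 0.0104). Amot, a regulator of the Hippo pathway (chromosome X, 145446425 to 145505181), fell from 4306 ± 199 to 1803 ± 38.8 (log2 fold change -1.25, SE 0.11, adjusted p = 4.43e-06). In all, 13 genes fell and 0 rose in limma, and 534 genes had an unadjusted p under 0.05. With the cell line as a block 63 fell and 23 rose, 86 in all, and the 13 were among them.

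In the definitive endoderm list 0 of 24 members rose, 3 fell and 21 were not called (0 rose and 4 fell when adjusted over the list alone). The other members that fell were Gata6 (chromosome 18, 11052064 to 11085635), from 122 ± 27.6 to 33.1 ± 13.9 (log2 fold change -1.90, SE 0.26, adjusted p = 0.00238), and Cxcr4, from 131 ± 25.9 to 33.7 ± 0.632 (log2 fold change -1.91, SE 0.36, adjusted p = 0.0465). In the anterior endoderm list 0 of 19 members rose, 3 fell and 16 were not called (0 rose and 6 fell when adjusted over the list alone). Beside Dkk1 these were Gsc, a homeobox gene of the organizer (chromosome 12, 104471209 to 104473330), from 205 ± 48.3 to 57.5 ± 21.1 (log2 fold change -1.85, SE 0.32, adjusted p = 0.0278), and Shisa2, from 282 ± 36.6 to 119.9 ± 4.82 (log2 fold change -1.22, SE 0.22, adjusted p = 0.0308). In the NODAL list 0 of 18 members rose, 1 fell and 17 were not called (0 rose and 2 fell when adjusted over the list alone). The WNT receptor Fzd5 fell from 1441 ± 200.4 to 859 ± 126 and the kinase gene Plk5 from 158 ± 32.4 to 71.2 ± 15. Cfc1, a NODAL co-receptor, stood at 61.3 ± 14.5 and 9.38 ± 2.81 with adjusted p = 0.0838, or 0.00166 with the block. Lhx1 stood at 718 ± 143 and 338 ± 228 (adjusted p = 0.357, 0.0455 with the block), and the NODAL and WNT antagonist Cer1 at 664 ± 129 and 327 ± 60.1 (adjusted p = 1, 0.00649 with the block). The streak gene T stood at 1800.5 ± 677 and 3870.3 ± 1493 and was not called (adjusted p = 1).

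As sets, 8 of the 33 fixed lists were called lower in EPI by camera with a preset correlation and 0 higher. The anterior endoderm list gave adjusted p = 3.08e-12, and adjusted p = 0.061 with an estimated correlation. The definitive endoderm list gave adjusted p = 9.02e-07, and adjusted p = 0.456 with an estimated correlation, and the NODAL list adjusted p = 0.000363, and adjusted p = 0.061 with an estimated correlation. In the primitive streak list 0 of 21 members rose, 2 fell and 19 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.00249, and adjusted p = 0.668 with an estimated correlation. In the axial mesendoderm list 0 of 15 members rose, 2 fell and 13 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.00453, and adjusted p = 0.456 with an estimated correlation. In the WNT antagonist list 0 of 16 members rose, 2 fell and 14 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.00818, and adjusted p = 0.456 with an estimated correlation. The members called in these 3 lists were Gsc, Gata6, Dkk1 and Shisa2, so the lists share genes. In the hypoxia list 0 of 22 members rose, 0 fell and 22 were not called (0 rose and 0 fell when adjusted over the list alone), with adjusted p = 0.0213, and adjusted p = 0.888 with an estimated correlation. In the epiblast list 0 of 19 members rose, 0 fell and 19 were not called (0 rose and 0 fell when adjusted over the list alone), with adjusted p = 0.0435, and adjusted p = 0.684 with an estimated correlation. Without line 7H the adjusted p rose to 0.127 for the epiblast list, 0.0602 for the axial list and 0.108 for the hypoxia list. Without 7H2 it was 0.0723 for the epiblast and 0.102 for the hypoxia list. With the cell line as a block, 3 more lists passed. These were the immediate early list upward (adjusted p = 0.102, blocked 0.00147, median 0.24, mean -0.05), the FGF list upward (0.139, blocked 0.0391, median 0.12, mean -0.02) and the endoplasmic reticulum stress list downward (0.0699, blocked 0.0127, median -0.15). None of the 3 had a called member, and camera with an estimated correlation and no block gave adjusted p = 0.888, 0.684 and 0.888.

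The EPI libraries with dTAG13 were shallower than those with DMSO, at an estimated 17.2 to 21 and 25.3 to 27.9 M reads. The EPI count was 6 without the 7H1 DMSO library, 3 without the 7H2 DMSO library, and 6, 20 and 5 without the dTAG13 library of 7H, 7H1 and 7H2. Fitting the 6 EPI libraries alone called 2 genes, and of the 9 genes named as called it kept Amot. With each EPI library left out in turn, Dkk1, Gata6 and Amot kept their calls. With each cell line left out in turn, Amot alone of the 9 kept it, and Dkk1 and Gata6 lost theirs without 7H and without 7H2.

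In PS, the genes lowered by dTAG13 included Sox17 and Cxcr4 of the definitive endoderm list, Pdgfra of the mesoderm list and Jag1 of the NOTCH list. Sox17 fell from 2203 ± 971 to 137 ± 79.8 (log2 fold change -4.13, SE 0.50, adjusted p = 0.000485). Its values were 1134, 2443 and 3031 with DMSO and 45.5, 175 and 191 with dTAG13 in lines 7H, 7H1 and 7H2. Cxcr4 fell from 814 ± 469 to 76.7 ± 48.4 (log2 fold change -3.38, SE 0.36, adjusted p = 8.73e-05). Sema6d, a transmembrane semaphorin (chromosome 2, 124089969 to 124667770), fell from 1085 ± 91.5 to 174 ± 75.3 (log2 fold change -2.74, SE 0.29, adjusted p = 7.68e-05). In all, 20 genes fell and 13 rose, and with the cell line as a block 162 fell and 200 rose, 362 in all, among them the 33.

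Of the definitive endoderm list, 0 of 24 members rose, 2 fell and 22 were not called (0 rose and 8 fell when adjusted over the list alone), with adjusted p = 2.64e-05, and adjusted p = 0.46 with an estimated correlation. The called members were Sox17 and Cxcr4. In the anterior endoderm list 0 of 19 members rose, 0 fell and 19 were not called (0 rose and 4 fell when adjusted over the list alone), with adjusted p = 0.000159, and adjusted p = 0.456 with an estimated correlation. Its member Gsc stood at 5660.1 ± 1704 and 3346 ± 1433 (adjusted p = 0.511, 0.0111 with the block). In the mesoderm list 0 of 27 members rose, 1 fell and 26 were not called (0 rose and 2 fell when adjusted over the list alone), with adjusted p = 0.0124, and adjusted p = 0.546 with an estimated correlation, and the called member was Pdgfra, from 1099 ± 232 to 215 ± 55.1. In the primitive streak list 0 of 21 members rose, 2 fell and 19 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.0175, and adjusted p = 0.701 with an estimated correlation. Lhx1 and Pdgfra fell there, Lhx1 from 22615 ± 3663 to 6959 ± 2049 (log2 fold change -1.73, SE 0.34, adjusted p = 0.0319). The T-box factor Eomes stood at 13859 ± 843 and 7829 ± 892 (adjusted p = 0.664, 0.00886 with the block). In the NOTCH list 0 of 17 members rose, 1 fell and 16 were not called (0 rose and 1 fell when adjusted over the list alone), with adjusted p = 0.0158, and adjusted p = 0.371 with an estimated correlation, and the member was the ligand Jag1 (chromosome 2, 137081456 to 137116644), from 1994 ± 252 to 815 ± 164 (log2 fold change -1.30, SE 0.18, adjusted p = 0.000661). In the WNT antagonist list 0 of 16 members rose, 0 fell and 16 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.0348, and adjusted p = 0.546 with an estimated correlation. In the list of mitochondrially encoded genes 0 of 13 members rose, 0 fell and 13 were not called (0 rose and 0 fell when adjusted over the list alone), with adjusted p = 0.0296, and adjusted p = 0.888 with an estimated correlation and a median log2 fold change of -0.18. Without line 7H the adjusted p rose to 0.133 for the streak, 0.0602 for the mesoderm, 0.127 for the WNT antagonist and 0.113 for the NOTCH list. Without 7H1 it was 0.0649 for the WNT antagonist, 0.0754 for the NOTCH and 0.228 for the mitochondrial list.

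Further genes were called in PS. The paired box gene Pax7 fell from 83 ± 12.7 to 8.78 ± 2.21, and the Iroquois genes Irx3 (chromosome 8, 91798525 to 91802067) and Irx5 fell from 599.9 ± 144 to 208 ± 55.4 and from 308 ± 59.9 to 69.9 ± 24.3. In the neurectoderm list, which holds Pax7 and Irx3, 0 of 20 members rose, 2 fell and 18 were not called (0 rose and 2 fell when adjusted over the list alone), with adjusted p = 0.454, and adjusted p = 0.888 with an estimated correlation. The protocadherin Pcdh8 fell from 597 ± 36.5 to 135 ± 42.3, the guidance receptor Robo1 from 1112 ± 261 to 515 ± 129, the synaptic organiser Cbln1 from 158 ± 72.2 to 42.1 ± 20.9 and the RhoGAP gene Dlc1 (chromosome 8, 36567751 to 36953143) from 3069 ± 477 to 906 ± 255. The collagen receptor Ddr1 rose from 1232 ± 88.7 to 2346 ± 276, and the transcription factor genes Csrnp1 and Klf3 from 444 ± 38.1 to 799 ± 109.8 and from 486 ± 49.1 to 849 ± 153. The zinc transporter Slc39a8 rose from 2059 ± 154 to 3511 ± 143, the imprinted gene Peg10 from 3411 ± 523 to 5691 ± 471 and Plekhf2 from 4769 ± 332 to 7862 ± 847.

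Both stress lists were called higher in PS with no member called over all genes. In the endoplasmic reticulum and integrated stress list 0 of 20 members rose, 0 fell and 20 were not called (7 rose and 0 fell when adjusted over the list alone), with adjusted p = 8.99e-07, and adjusted p = 0.546 with an estimated correlation. Its median log2 fold change was 0.38. Trib3, a pseudokinase induced by that response, stood at 573 ± 116 and 1335 ± 441 (adjusted p = 0.107, 0.0178 with the block). In the immediate early list 0 of 21 members rose, 0 fell and 21 were not called (2 rose and 0 fell when adjusted over the list alone), with adjusted p = 6.76e-05, and adjusted p = 0.576 with an estimated correlation. Fos stood at 334 ± 117 and 741 ± 249 (adjusted p = 0.0739, 4.37e-05 with the block). The other 24 lists, the neurectoderm list among them, were not called in PS.

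The PS count was 15 without the 7H1 DMSO library, 13 without the 7H2 DMSO library, 228 without the 7H dTAG13 library and 8 without the 7H1 dTAG13 library. The 6 PS libraries fitted alone called 11 genes, and of the 19 named as called 6 kept their call with each library left out in turn: Sox17, Cxcr4, Sema6d, Irx3, Dlc1 and Jag1. Of these, Sox17, Cxcr4, Irx3 and Jag1 lost it in the 6 libraries alone and without line 7H1, Sox17 also without 7H2, and Dlc1 without 7H. With each line left out, Sema6d alone of the 19 kept its call. The PS libraries also parted otherwise than by treatment. Mitochondrial genes took 1.77 to 1.85% of DMSO 7H, DMSO 7H1 and dTAG13 7H, and 1.34 to 1.39% of DMSO 7H2, dTAG13 7H1 and dTAG13 7H2. This structure is partly confounded with dTAG13, so the genes and lists called in PS may carry some of it.

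**Figure D3:**
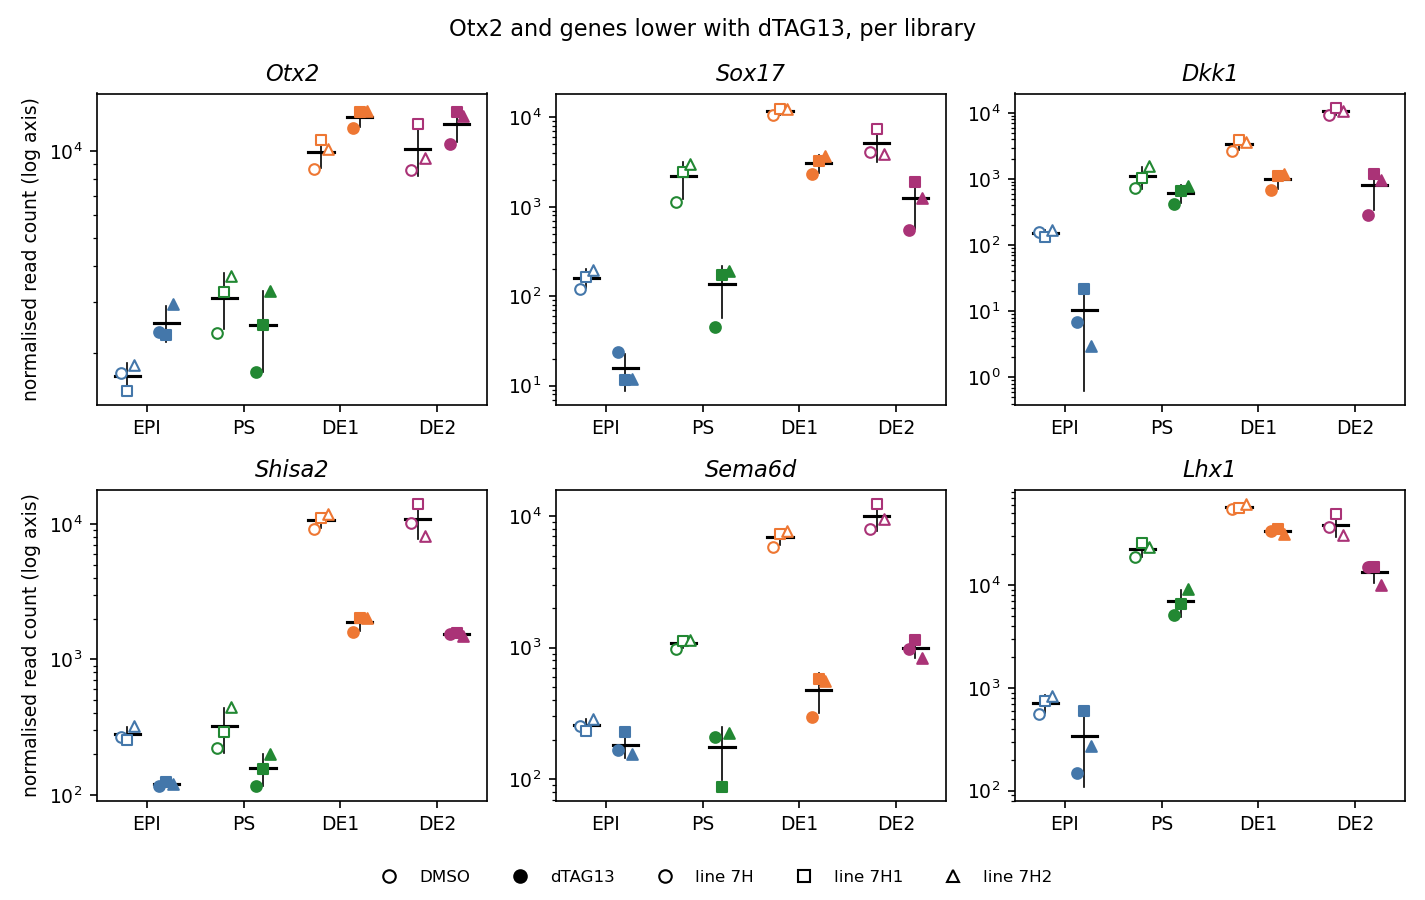
Normalised read count (log axis) per library at each stage for Otx2 and 5 genes lower with dTAG13 in at least 1 stage; open symbols DMSO, filled symbols dTAG13, symbol shape the cell line, horizontal line the mean and vertical line the SD of 3 libraries. Sox17 in PS lies at 1134, 2443 and 3031 with DMSO and 45.5, 175 and 191 with dTAG13, and Otx2 was not called at any stage.

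In DE1, dTAG13 lowered 6 and raised 1 of 22 genes of the hypoxia and glycolysis list, and raised 5 and lowered 3 of 19 WNT target genes. Neither list was called with an estimated correlation (adjusted p = 0.701 and 0.561). Shisa2 fell from 10676 ± 1411 to 1881 ± 249 (log2 fold change -2.50, SE 0.22, adjusted p = 1.5e-07). Cdh1 fell from 18283 ± 1162 to 6640.5 ± 213 (log2 fold change -1.46, SE 0.08, adjusted p = 1.54e-10). Nkx6-1, a homeobox gene of pancreatic and neural progenitors (chromosome 5, 101658139 to 101664996), rose from 35.9 ± 8.5 to 1179 ± 175 (log2 fold change 5.01, SE 0.46, adjusted p = 2.21e-07). Lgr5, a receptor for R-spondins and a WNT target (chromosome 10, 115450311 to 115587780), rose from 620.5 ± 54.6 to 3548 ± 283 (log2 fold change 2.51, SE 0.28, adjusted p = 5.19e-06). In all, 562 genes rose and 605 fell, of these 323 and 308 at least 2-fold. With the cell line as a block 1216 rose and 1160 fell, 2376 in all, and 1160 of the 1167 were among them. Rescaling to equal totals gave 733 rises and 490 falls.

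In the anterior endoderm list 1 of 19 members rose, 4 fell and 14 were not called (2 rose and 5 fell when adjusted over the list alone), with adjusted p = 0.0618, or 0.0239 with the block. Sfrp5 (chromosome 19, 42197971 to 42202252) fell from 1045 ± 624 to 96.5 ± 34 (log2 fold change -3.23, SE 0.71, adjusted p = 0.00545), Isl1 from 49 ± 18.7 to 6.67 ± 2.96 and Dkk1 from 3405 ± 679 to 993 ± 279. In the definitive endoderm list 1 of 24 members rose, 3 fell and 20 were not called (2 rose and 6 fell when adjusted over the list alone), with adjusted p = 0.2. Sox17 fell from 11775 ± 1075 to 3092 ± 707 (log2 fold change -1.95, SE 0.50, adjusted p = 0.0196) and Prdm1 from 3409 ± 353 to 1064 ± 53.5. The hepatic and intestinal factor Hnf4a was at 27.4, 57.4 and 113 with DMSO and 1.95, 0 and 0 with dTAG13. Sema6d fell from 6913 ± 944 to 479 ± 158 (log2 fold change -3.90, SE 0.29, adjusted p = 1.04e-08), and Pax7, Irx3 and Robo1 were lower again (log2 fold changes -3.50, -1.54 and -1.77). Tcerg1l stood at 201, 222 and 229 and 0.88, 0 and 0, and the eye field gene Rax at 103, 129 and 129 and 0, 0 and 2.01. Ermn stood at 121, 157 and 141 and was listed at 0 in all 3 dTAG13 libraries. Alx1 fell from 334 ± 83.9 to 8.14 ± 3.57, the troponin gene Tnnt1 from 520.4 ± 156 to 19.5 ± 12.1, Casr from 589.8 ± 174 to 23.8 ± 3.58 and Fam213a from 1573 ± 125 to 71.8 ± 4.29.

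The hypoxia and glycolysis list was called lower in DE1 with adjusted p = 0.000363, and adjusted p = 0.701 with an estimated correlation. In this list 1 of 22 members rose, 6 fell and 15 were not called (1 rose and 11 fell when adjusted over the list alone). The glucose transporter Slc2a1 (chromosome 4, 119108711 to 119137983) fell from 10330 ± 1405 to 2277 ± 416 (log2 fold change -2.19, SE 0.27, adjusted p = 1.92e-05), hexokinase Hk2 from 4572 ± 597 to 2518 ± 278 and the angiogenic factor Vegfa from 3474 ± 124 to 1948 ± 49.4. The laminin gene Lamc1 fell from 22688 ± 1896 to 10912 ± 701 within the extracellular matrix list, where 2 of 27 members rose, 3 fell and 22 were not called (3 rose and 3 fell when adjusted over the list alone). That list gave adjusted p = 0.2 upward, or 0.0239 with the block. Of the mitochondrially encoded genes, 0 of 13 members rose, 0 fell and 13 were not called (0 rose and 0 fell when adjusted over the list alone), with adjusted p = 0.0618 downward, or 0.0113 with the block.

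The WNT target list was called higher in DE1 with adjusted p = 0.0435, and adjusted p = 0.561 with an estimated correlation, 0.0791 with equal totals and 0.0506 with fry. In this list 5 of 19 members rose, 3 fell and 11 were not called (8 rose and 3 fell when adjusted over the list alone). Beside Lgr5, the feedback inhibitor Axin2 rose from 264 ± 9.44 to 764 ± 45.6 (log2 fold change 1.53, SE 0.30, adjusted p = 0.00251) and Apcdd1 from 67.7 ± 29.6 to 244 ± 47.3, while Sp8 stood at 12.4, 0 and 0 and 92.4, 19.4 and 26.2. The member Dkk1 was among the falls. The ligand Wnt3 rose from 391 ± 26.3 to 858 ± 165, and the activin antagonist Fst from 27.6 ± 3.8 to 333 ± 15.3. In the BMP list 3 of 18 members rose, 1 fell and 14 were not called (4 rose and 1 fell when adjusted over the list alone), with adjusted p = 0.109. Bmp4 (chromosome 14, 46383520 to 46390669) rose from 55.1 ± 5.34 to 274 ± 11.5 (log2 fold change 2.30, SE 0.49, adjusted p = 0.00424) and the homeobox gene Msx1 from 21.7 ± 13.8 to 142 ± 33.8. The axon guidance list was called higher with adjusted p = 0.0469, and adjusted p = 0.668 with an estimated correlation. In this list 5 of 29 members rose, 3 fell and 21 were not called (9 rose and 4 fell when adjusted over the list alone), with the ephrin receptor Epha1 from 374 ± 21.9 to 970.1 ± 61.2 among the rises and Sema6d and Robo1 among the falls. The axon guidance list gave adjusted p = 0.0608 without 7H, 0.0821 without 7H1 and 0.11 with equal totals.

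Markers of other cell types were also among the DE1 calls. In the trophectoderm list 2 of 12 members rose, 2 fell and 8 were not called (2 rose and 2 fell when adjusted over the list alone), with adjusted p = 0.785. Its keratin Krt7 rose from 2232 ± 151 to 5422 ± 373 and the AP-2 factor Tfap2c from 1983 ± 128 to 5366 ± 281. In the mesoderm list 1 of 27 members rose, 1 fell and 25 were not called (1 rose and 1 fell when adjusted over the list alone), with adjusted p = 0.148, and the VEGF receptor Kdr rose from 92.4 ± 28.2 to 529 ± 121. In the NOTCH list 4 of 17 members rose, 3 fell and 10 were not called (4 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.912, and the effector Hey1 rose from 1405 ± 269.7 to 4864 ± 181. The NOTCH median was -0.12 and the mean -0.02, beside a test that was upward here and downward with the block and with equal totals. Among the further large rises were Tnfsf9 from 51.4 ± 37 to 658 ± 122, the cadherin Cdh23 from 117 ± 73.6 to 1277 ± 49.5, the zinc transporter Slc30a3 from 129 ± 66.6 to 1305 ± 103, the glutamate receptor Grm6 from 17.3 ± 8.73 to 169 ± 50.3 and the junction molecule Jam2 from 17 ± 5.67 to 164 ± 45.2. Of 62 genes at least 8-fold higher in PS than in DE2 vehicle cells, a choice without DE1 libraries, 11 were called higher with dTAG13 in DE1 and 0 lower, against 551 and 605 of the other 14975 genes.

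The DE1 count was 718 and 768 without the DMSO library of 7H1 and 7H2, and 776 and 753 without the dTAG13 library of 7H and 7H1. The calls of Dkk1, Fst and Krt7 were lost without any 1 of the 6 libraries, those of Sox17, Kdr and Tfap2c without the DMSO library of 7H1 or 7H2 or the dTAG13 library of 7H or 7H1, and that of Cdh23 without the DMSO library of 7H1. With a line left out the count was 380 to 702, and 17 of the 42 genes named as called lost their call without at least 1. Beside the 7 above these were Sfrp5, Isl1, Hnf4a and Sp8 without 7H1 and without 7H2, Wnt3 and Grm6 without 7H and without 7H2, Vegfa without 7H, and Hk2, Axin2 and Bmp4 without 7H2. The 6 libraries alone called 2304 and kept all 42 calls.

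In DE2, dTAG13 lowered 8 and raised 2 of 19 genes of the anterior endoderm list, lowered 7 and raised 2 of 20 of the neurectoderm list, and raised 10 and lowered 0 of 20 of the endoplasmic reticulum and integrated stress list. None of the 3 lists was called with an estimated correlation (adjusted p = 0.561, 0.371 and 0.668). Dkk1 fell from 10732 ± 1312 to 824 ± 479 (log2 fold change -3.93, SE 0.52, adjusted p = 2.3e-05). Nrp2, a semaphorin receptor (chromosome 1, 62703285 to 62818695), fell from 7879.7 ± 1935 to 574 ± 249.8 (log2 fold change -3.82, SE 0.33, adjusted p = 6.52e-08). Wscd1 (chromosome 11, 71749920 to 71789647) fell from 2759 ± 98.8 to 24.1 ± 10.1 (log2 fold change -6.86, SE 0.31, adjusted p = 2.28e-12). Cdh2, the neural and mesenchymal cadherin (chromosome 18, 16588877 to 16809246), rose from 1314 ± 808 to 8037 ± 1596 (log2 fold change 2.76, SE 0.25, adjusted p = 1.48e-07). In all, 1301 genes rose and 1250 fell, of these 442 and 799 at least 2-fold, so falls prevailed among the larger changes. With the cell line as a block 2120 rose and 2019 fell, 4139 in all, and 2540 of the 2551 were among them.

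The anterior endoderm list was called lower in DE2 with adjusted p = 0.00467, and adjusted p = 0.561 with an estimated correlation. In this list 2 of 19 members rose, 8 fell and 9 were not called (3 rose and 8 fell when adjusted over the list alone). Gsc fell from 8964 ± 1832 to 1298 ± 474 (log2 fold change -2.85, SE 0.32, adjusted p = 3.28e-06), Isl1 from 1673 ± 428 to 69.4 ± 63.6 (log2 fold change -4.92, SE 0.61, adjusted p = 6.24e-06), Sfrp5 from 2949 ± 381 to 158 ± 88.7 and Shisa2 from 10817 ± 3028 to 1528 ± 39.9, while Cyp26a1 rose from 5091 ± 1522 to 15619 ± 2081. In the definitive endoderm list 3 of 24 members rose, 5 fell and 16 were not called (5 rose and 5 fell when adjusted over the list alone), with adjusted p = 0.687. Gata4 fell from 8452 ± 2039 to 2399 ± 978 and Cxcr4 from 6940.4 ± 1561 to 2222 ± 342. In the axial mesendoderm list 0 of 15 members rose, 5 fell and 10 were not called (0 rose and 5 fell when adjusted over the list alone), with adjusted p = 0.374, and Lhx1 fell from 38988 ± 9324 to 13318 ± 2861. The axial median was 0.22, beside a mean of -0.60 and a downward test. In the NODAL list 0 of 18 members rose, 3 fell and 15 were not called (0 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.0699 downward, or 0.0102 with the block. In the hypoxia list 1 of 22 members rose, 4 fell and 17 were not called (1 rose and 5 fell when adjusted over the list alone), with adjusted p = 0.13 downward, or 0.00394 with the block, and Slc2a1 fell from 32447 ± 9573 to 8410.2 ± 3437.

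The neurectoderm list was called lower in DE2 with adjusted p = 0.00473, and adjusted p = 0.371 with an estimated correlation. In this list 2 of 20 members rose, 7 fell and 11 were not called (2 rose and 7 fell when adjusted over the list alone). The paired box genes Pax7 and Pax3 fell from 483 ± 187 to 4.03 ± 2.57 and from 262 ± 47.3 to 6.26 ± 2.05, and the adhesion molecule Ncam1 fell from 1833 ± 107 to 244 ± 101 (log2 fold change -2.98, SE 0.25, adjusted p = 3.01e-08). Fezf1, a zinc finger gene of the forebrain, stood at 166, 128 and 252 with DMSO and was listed at 0 in all 3 dTAG13 libraries. The homeobox gene Tlx1 stood at 362, 1152 and 764 and 0, 0 and 1.7, and the RNA-binding gene Rbm24 at 1159.7, 1926 and 1170.4 and 4.01, 0 and 26.1. The neurofilament gene Nefh stood at 561, 368 and 201 and 4.02, 0 and 3.07, and the glutamate receptor gene Grin2c at 378, 1086 and 609 and 10.3, 0 and 9.27. Of the axon guidance list, 6 of 29 members rose, 6 fell and 17 were not called (6 rose and 7 fell when adjusted over the list alone), with adjusted p = 0.987, and Sema6d and Robo1 fell from 9922 ± 2273 to 991 ± 155 and from 20742 ± 3875 to 6678 ± 1461. The median of that list was 0.27, beside a mean of -0.05 and a test that was downward here and upward with the block and with equal totals. Fam46c fell from 5163 ± 401 to 54.6 ± 40.3, the NOTCH effector Hey2 from 195 ± 109 to 7.29 ± 6.55 and the cardiac T-box gene Tbx20 from 1329 ± 416 to 105 ± 46.6. In the epiblast list 2 of 19 members rose, 6 fell and 11 were not called (2 rose and 8 fell when adjusted over the list alone), with adjusted p = 0.0591 downward, or 0.00131 with the block.

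The lists of signalling pathways held changes in both directions in DE2. In the WNT target list 4 of 19 members rose, 2 fell and 13 were not called (8 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.333, and Lgr5 rose from 1081 ± 140.4 to 4388 ± 712. In the primitive streak list 3 of 21 members rose, 4 fell and 14 were not called (5 rose and 4 fell when adjusted over the list alone), with adjusted p = 0.803. Wnt3 rose from 115 ± 29.5 to 345 ± 134 and Mixl1 from 86.7 ± 71.5 to 378 ± 140.5. In the posterior endoderm list 2 of 15 members rose, 1 fell and 12 were not called (2 rose and 1 fell when adjusted over the list alone), with adjusted p = 0.803, and Wnt5b rose from 45.4 ± 38.9 to 412 ± 216. In the BMP list 4 of 18 members rose, 3 fell and 11 were not called (5 rose and 4 fell when adjusted over the list alone), with adjusted p = 0.874, and Bmp4 rose from 86.9 ± 88.8 to 695 ± 157 (log2 fold change 3.49, SE 0.49, adjusted p = 2.79e-05). In the FGF list 5 of 23 members rose, 7 fell and 11 were not called (6 rose and 8 fell when adjusted over the list alone), with adjusted p = 0.901. Fgf10 rose from 875 ± 254 to 3323 ± 1526 and the ETS factor Etv5 fell from 2703 ± 690.4 to 568 ± 374. In the retinoic acid list 3 of 16 members rose, 3 fell and 10 were not called (3 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.822. The retinol dehydrogenase Rdh10 rose from 476 ± 306 to 2251 ± 412 and the receptor Rarb fell from 1096 ± 532 to 91 ± 38.3. In the NOTCH list 5 of 17 members rose, 1 fell and 11 were not called (5 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.901, and Jag1 and Hey1 rose from 595 ± 121 to 1511 ± 409.7 and from 359 ± 223 to 1369 ± 462. Median, mean and test differed in sign for 3 of these lists. The BMP and posterior endoderm lists had medians of -0.25 and -0.40 beside means of 0.26 and 0.30 and an upward test, and the NOTCH list had a median of -0.17 and a mean of -0.34 beside an upward test.

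The endoplasmic reticulum and integrated stress list was called higher in DE2 with adjusted p = 0.000363, and adjusted p = 0.668 with an estimated correlation. In this list 10 of 20 members rose, 0 fell and 10 were not called (12 rose and 0 fell when adjusted over the list alone). The glutathione-degrading enzyme Chac1 rose from 266 ± 119 to 988 ± 699, the stress regulator Nupr1 from 36.6 ± 14.3 to 257 ± 129.7, the serine synthesis enzyme Psat1 from 3205 ± 1031 to 5603 ± 2095 and the unfolded protein response factor Xbp1 from 1517 ± 319 to 2113 ± 86.8. The largest rises over all genes included Nkx6-1 from 59.5 ± 15.5 to 1018 ± 392 (log2 fold change 4.04, SE 0.46, adjusted p = 2.04e-06) and the gap junction gene Gjb2 from 20.3 ± 2.56 to 450.4 ± 254 (log2 fold change 4.21, SE 0.52, adjusted p = 5.91e-06). Slc16a12 (log2 fold change 4.88), Adcy8 (4.67), Efhd1 (4.61) and Foxd1 (4.10) rose too. Klk1b3 rose from 60.6 ± 24.9 to 1271 ± 678, and is uncertain because it belongs to a family of near-identical kallikrein genes that share reads. The metalloprotease Adamts18 stood at 39.8, 0 and 0 with DMSO and 346, 217 and 119 with dTAG13. In the trophectoderm list 2 of 12 members rose, 3 fell and 7 were not called (2 rose and 3 fell when adjusted over the list alone), with adjusted p = 0.242, and Krt7 rose from 1654 ± 397 to 9234 ± 2294 (log2 fold change 2.48, SE 0.35, adjusted p = 3.55e-05).

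The DE2 count was 1771 to 2476 without a library and 998 to 1770 without a line. The 6 libraries alone gave 1564, under DE1 (2304), so the stage order rests on the fit. Of the 50 genes named as called, 49 kept their call with each library left out, and Psat1 lost it without the 7H1 DMSO or the 7H dTAG13 library. With each cell line left out 42 kept it. Chac1 and Psat1 lost it without 7H, Cxcr4, Mixl1, Psat1 and Xbp1 without 7H1, and Gata4, Lhx1, Foxd1, Mixl1 and Xbp1 without 7H2. In the 6 libraries alone Wnt5b, Chac1, Psat1 and Xbp1 lost it.

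**Figure D4:**
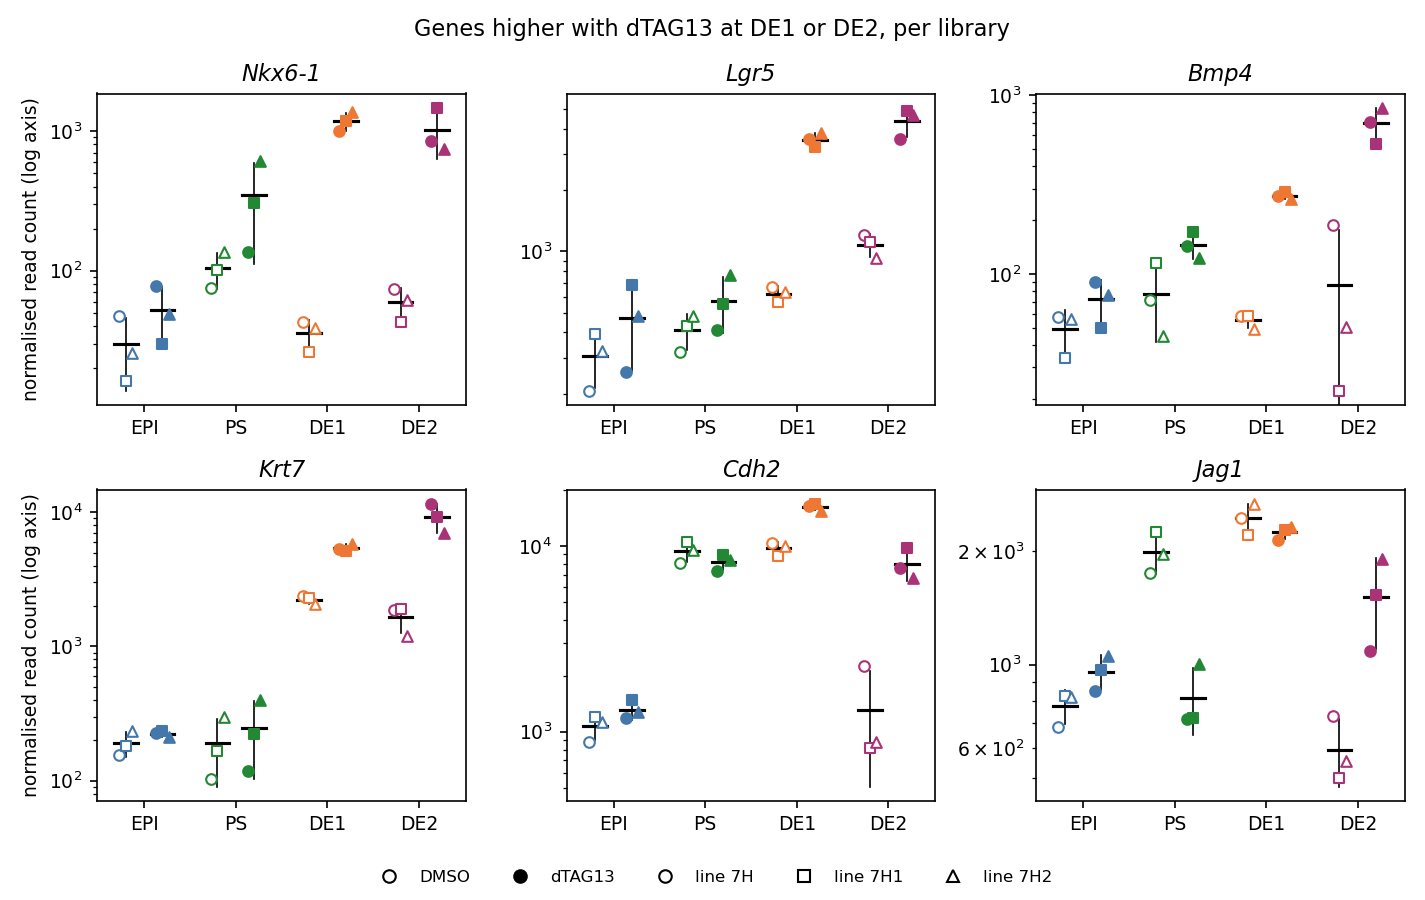
Normalised read count (log axis) per library at each stage for 6 genes higher with dTAG13 in DE1 or DE2; open symbols DMSO, filled symbols dTAG13, symbol shape the cell line, horizontal line the mean and vertical line the SD of 3 libraries, drawn to the axis floor where the SD exceeds the mean. Cdh2 in DE2 stood at 1314 ± 808 with DMSO and 8037 ± 1596 with dTAG13, and Jag1 was called lower in PS and higher in DE2.

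**Figure D5:**
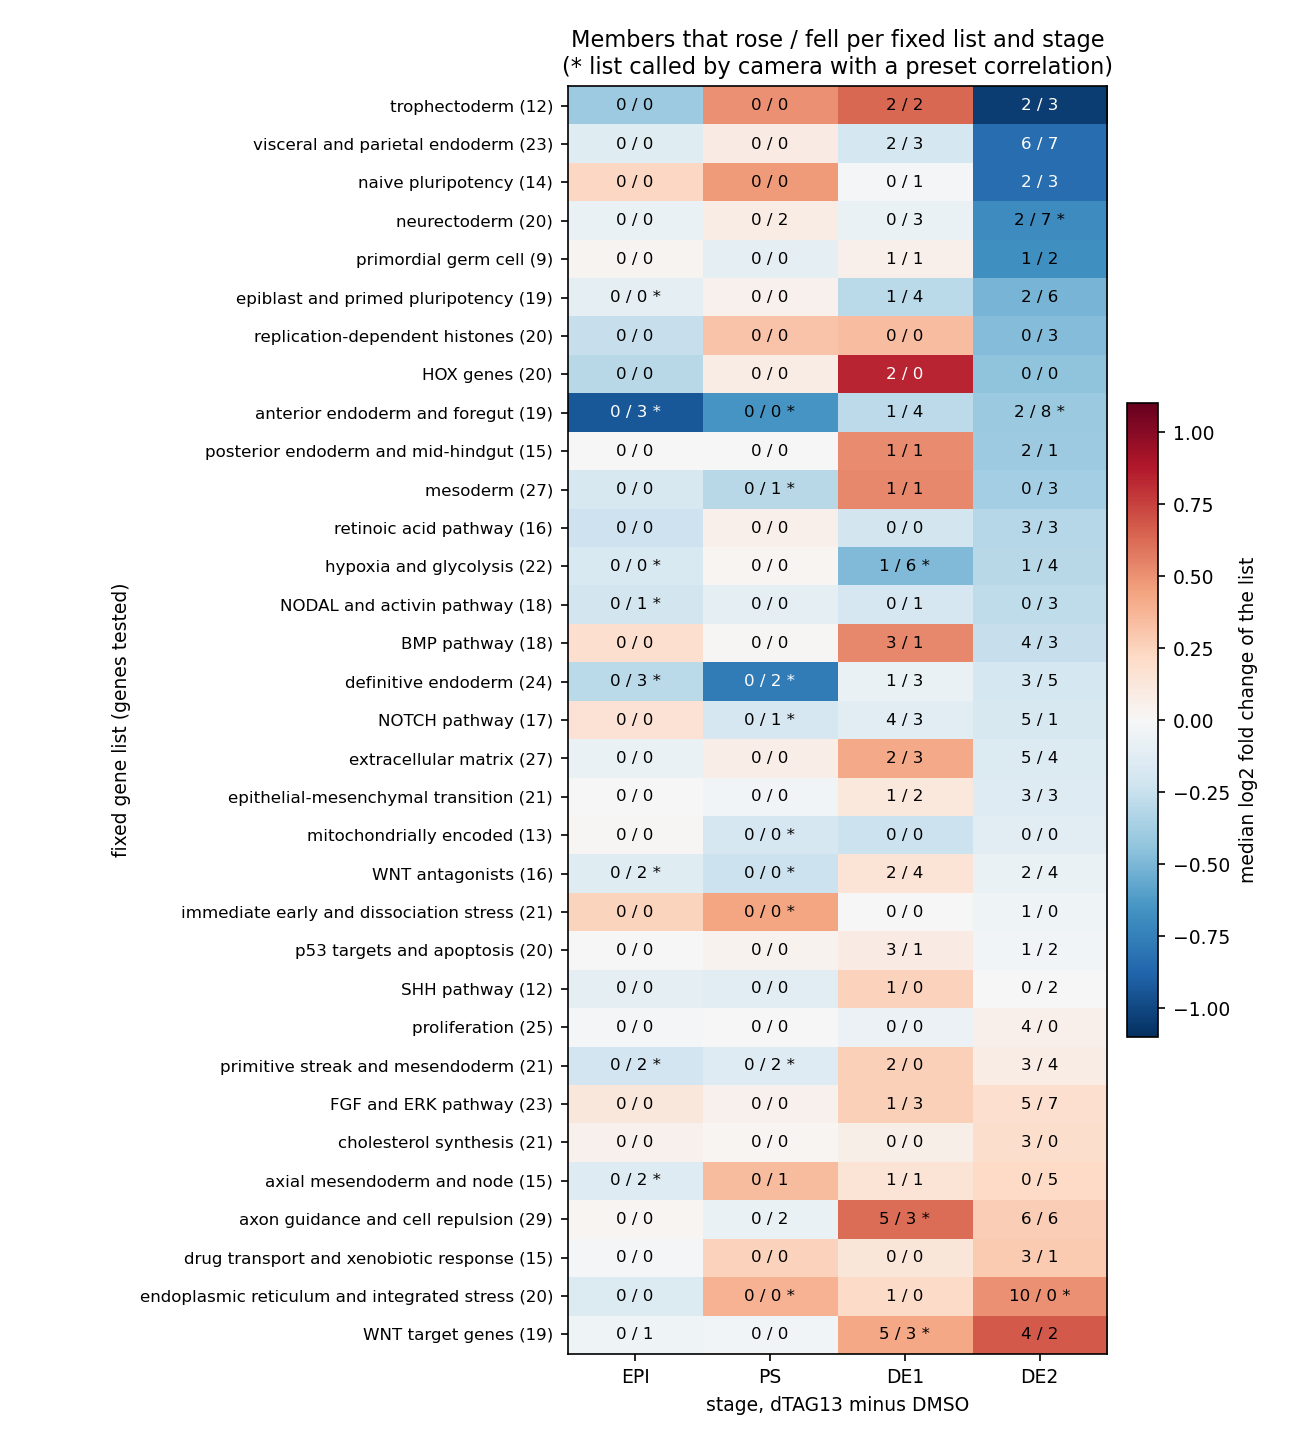
Fixed gene lists (number of genes tested in brackets) against stage, coloured by the median log2 fold change of dTAG13 over DMSO, with the members that rose and fell in each cell and an asterisk where the list was called by camera with a preset correlation. Of 132 list tests 23 were called, and none of them with an estimated correlation.

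Genes that fell were shared between each pair of the 4 stages more often than independent lists would share them. Between DE1 and DE2, 244 genes rose in both against 48.6 for independent lists, and 291 fell in both against 50.3 (Fisher's exact test, adjusted p = 9.93e-114 and 1.62e-157). Of the genes called in both, 51 of 586 had opposite signs here, 3 of 21 between PS and DE2, 2 of 17 between PS and DE1 and 1 of 9 between EPI and DE2, and 0 of 7 and 0 of 3 between EPI and DE1 or PS. Between PS and DE2, 15 of the 20 genes that fell in PS fell again against 1.66 (adjusted p = 2.4e-12), and between PS and DE1 11 did against 0.805 (1.48e-10). Between PS and DE1 4 genes rose in both against 0.486 (0.00158). Of the 13 genes that fell in EPI, 8 fell in DE2 against 1.08 (3.37e-06), 7 in DE1 against 0.523 (5.5e-07) and 3 in PS against 0.0173 (1.14e-06). These 3 were Sox17, Amot and Cxcr4. Between PS and DE2, 3 genes rose in both against 1.12, which was not called (adjusted p = 0.128). The 4 comparisons had separate control libraries, but they used the same 3 lines and took the spread of each gene from 1 common fit. Genes with a small spread can thus be called at several stages together. Fisher's test also takes genes as independent, so its p-values can overstate the sharing. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.322 between DE1 and DE2 and 0.0631 to 0.127 for the other pairs.

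Genes that changed along the vehicle conversion were then followed under dTAG13. The sets were the 200 strongest risers and 200 strongest fallers of a step that shares no library with the stage tested, so they were chosen on these samples and are not independent evidence of direction. By camera with a preset correlation the rising sets were called lower in all 4 stages, and with an estimated correlation in none (adjusted p = 0.355, 0.345, 0.109 and 0.345 in EPI to DE2). Fry gave 0.224 and 0.114 in EPI and PS, and 0.00012 and 0.000857 in DE1 and DE2. In EPI 0 rose and 5 fell (preset adjusted p = 6.51e-06), and in PS 0 rose and 11 fell (1.42e-08). In DE1 10 rose and 77 fell (1.74e-15), and in DE2 31 rose and 73 fell (2.04e-07). Falling genes were not called in EPI (0 rose, 0 fell, adjusted p = 0.307). They were called higher in PS (2 rose, 0 fell, 7.11e-05) and DE2 (54 rose, 14 fell, 5.6e-05) and lower in DE1 (20 rose, 23 fell, 0.000144), with adjusted p = 0.423, 0.423 and 0.44 with an estimated correlation. The balance of called members in DE1 was the opposite with equal totals (21 rose, 12 fell) and without 7H (21 and 5), 7H1 (19 and 3) or 7H2 (6 and 4). For falling genes the adjusted p in DE1 rose to 0.0876 without line 7H and 0.571 without 7H1, and in DE2 to 0.571 without 7H1.

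Differences of the dTAG13 effect between successive stages were tested directly. From EPI to PS 2 genes were called, with 39 under the cell line block. Jag1 changed by -1.60 (log2, SE 0.25, adjusted p = 0.0371). Rap1gap2 was listed at 0 in all 3 PS DMSO libraries and stood at 34.2, 75.8 and 15 with dTAG13, and in EPI at 86.7, 29.7 and 183 and 47, 118 and 42 (adjusted p = 0.0394, 0.0537 with the block). From PS to DE1 the effect was higher for 123 genes and lower for 199, with 954 under the block, and from DE1 to DE2 higher for 439 and lower for 456, with 2258 under the block. With equal totals the last comparison gave 338 higher and 552 lower. The first of these counts was 0 without the EPI DMSO library of 7H or 7H2, the EPI dTAG13 library of 7H or 7H2, the PS DMSO library of 7H2 or the PS dTAG13 library of 7H1. It was 1 without the PS DMSO library of 7H1 or the PS dTAG13 library of 7H, 4 without the PS dTAG13 library of 7H2 and 5 without the EPI dTAG13 library of 7H1. The second count was 208 and 197 without the DE1 DMSO library of 7H1 and 7H2.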

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

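The tests of stage mixture and of stress, and the counting of splits by the treatment they keep, were chosen after the results were seen, and the counts over all splits were planned. The genes of the mixture tests were chosen again after a first choice that shared DE1 libraries with the test, and a like test in DE2 was dropped because no later stage allows a separate choice. The results in this part are differences of the dTAG13 effect between stages, tested as interactions in limma with Benjamini-Hochberg adjustment, on the log2 scale. Fitted differences of genes with zeros depend on the pseudocount, so their library values follow.

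Between EPI and PS 2 genes differed, Rap1gap2 (5.47) and Jag1 (-1.60). Between PS and DE1 322 differed. The largest increases were Cdh23 (5.04), Adcy8 (4.47), Jam2 (3.92), Dach1 (3.72) and Nell2 (3.53). The largest decreases were Rap1gap2 (-8.25), Tcerg1l (-8.05), Naip6 (-5.84), Tnnt1 (-5.35) and Alx1 (-4.39). Between DE1 and DE2 895 differed. The largest increases were Clip4 (6.68, adjusted p = 0.0371, 0.0765 with the cell line as a block), Hnf4a (6.16), Efhd1 (5.47), Serpinb6c (5.12) and Alx1 (4.78). Among the largest decreases were Best2 (-9.10), Pyy (-7.37), Rbm24 (-6.31) and Tlx1 (-6.02). With each cell line left out in turn, Tcerg1l and Rap1gap2 between PS and DE1 alone kept their calls among the genes named here. Naip6 and Serpinb6c belong to families of similar genes and are uncertain.

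Rap1gap2 in DE1 stood at 428, 217 and 339.5 with DMSO and 28.2, 31.7 and 50.5 with dTAG13. Naip6 went from 112, 152 and 112 to 3.65, 10.7 and 0 there and Serpinb6c from 116, 163 and 160.1 to 2.74, 0 and 15. Adcy8 went from 20.2, 0 and 16.5 to 109.5, 134 and 203. Clip4 stood at 76.5, 228 and 99.2 and 0, 0 and 28.1 in DE1 and at 38.2, 87.1 and 92.5 and 178, 183 and 172 in DE2. In DE2 Hnf4a stood at 41.7, 211 and 58.9 and 16.6, 299.8 and 584, Pyy at 99.3, 401 and 243 and 0.847, 4.74 and 13.9 and Best2 at 239.7, 563 and 361 and 0, 0 and 52.3.

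Other splits of the same libraries were counted for each comparison. The 6 libraries of a 3 against 3 comparison give 10 splits, so the smallest share is 0.1 and the splits are too few for a share under 0.05. In EPI 3 of 10 splits called at least the real 13 genes, and the highest other called 222, with DMSO 7H, dTAG13 7H and dTAG13 7H2 against the rest. In PS 2 of 10 called at least 33, and the highest other called 1661. That split set DMSO 7H, DMSO 7H1 and dTAG13 7H against the rest, and points to a structure of the samples other than treatment. Mitochondrial genes took 1.85, 1.77 and 1.8% of these 3 libraries, and 1.39, 1.37 and 1.34% of DMSO 7H2, dTAG13 7H1 and dTAG13 7H2. The 10 highest genes took 5.72, 5.84 and 5.74%, and 6.28, 6.16 and 6.27%. The split parts the 7H1 pair, so the cell line block does not remove this structure in full, and it is partly confounded with dTAG13. Among splits parting all 3 pairs of lines, the highest other called 0 in EPI and 1 in PS, while the splits with more calls keep the libraries of a line together. In DE1 1 of 10 called 1167 (highest other 2) and in DE2 1 of 10 called 2551 (highest other 112). For the steps between stages 1 of 10 reached the real 4132, 6633 and 5914, and the highest others called 1, 0 and 5.

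For the differences of effects 100 splits were drawn. Between EPI and PS 25 reached the real 2 (highest other 2164), so over all splits chance was not excluded. Of the 75 that keep the treatments of neither stage 12 reached 2, but 0 of the 5 among them that part all 6 pairs of lines as the real split does (highest 1), which are too few for a share under 0.05. The splits with most calls keep libraries of a line together and contain the PS split that called 1661. Between PS and DE1 7 reached 322 (highest other 799). The split with 799 swaps the treatments of 1 whole stage and 4 others keep the treatments of DE1, so they carry a dTAG13 effect and the share does not decide on chance. Of the 78 splits that keep the treatments of neither stage 1 reached 322, with 469, and the 8 of these that part all 6 pairs called at most 1. Between DE1 and DE2 3 reached 895, a share under 0.05. The highest other called 2455, also a swap of 1 whole stage. A further one called 1118 and kept the treatments of DE2, so this share does not decide on chance either. Of the 78 that keep the treatments of neither stage 0 reached it (highest 60, and 0 in the 8 that part all 6 pairs). Splits that keep neither treatment mix dTAG13 and DMSO libraries, which puts the dTAG13 effects into the residual spread. Their low counts therefore do not test whether the stages have equal effects.

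In DE1, genes of the PS stage were higher with dTAG13: of 62 genes at least 8-fold above DE2 in PS vehicle cells, with at least 500, 11 were called higher and 0 lower, against 551 and 605 of the other 14975 genes. No DE1 library took part in this choice. The set of the 200 strongest fallers from PS to DE2 did not show it (20 rose, 23 fell). Cells left at the PS stage would raise genes of that stage. The first test run, the share of called genes that were lower, gave 0%, as predicted for left-over cells. It restates the counts that prompted it, so it lends no support. The second, chosen after the first was seen, asked whether 1 share of PS cells could account for the 62 genes together. Whatever the share, at least 43.5% of the genes had a 95% interval over the cell lines that left it out (at a share of 2%, with 27.4% above and 16.1% under it). The test takes left-over cells to hold PS vehicle levels and all other cells DE1 vehicle levels, while 1167 genes were called in DE1. Some of the 62 genes had fallen little by DE1, such as Cachd1 from 5199 to 3290, with an implied share of 151% (95% interval 19.1 to 283). So the test cannot tell left-over cells from other changes, and both stay open. A slower conversion without OTX2 is possible but was not tested.

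The endoplasmic reticulum and integrated stress list was higher in PS and DE2 (medians 0.38 and 0.50) with a preset correlation but was not called with an estimated one (adjusted p = 0.349 and 0.385, adjusted in this paragraph over the 8 tests of the 2 stress lists and not over all list tests as in the report). Of its 20 members 0 were called in PS and 10 in DE2, and the medians were -0.15 in EPI and 0.21 in DE1. Handling at harvest would raise the immediate early list too. In PS it rose (median 0.44, 17 of 21 members above 0, adjusted p = 1.02e-05 with a preset and 0.349 with an estimated correlation), which goes with handling and leaves it open there. In DE2 its members went both ways (median -0.0456, 10 of 21 above 0, adjusted p = 0.919 with an estimated correlation), which decides nothing. An effect of dTAG13 itself at any stage would raise the stress list in EPI too, where 3 of 20 members lay above 0. It would also give no difference between stages, while 19 of 20 members lay above 0 for PS minus EPI. The lowest adjusted p of a difference (camera, over 6 tests) was 1.19e-09 with a preset correlation but 0.205 with an estimated one. The members move together (estimated correlation 0.421), so their counts do not settle this explanation, which stays open. No dTAG13 treatment of untagged cells was analysed here. A response to the loss of OTX2 may also account for the list and was not tested.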

How the results depend on the processing

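Only the setting without genes that have a 0 beside 50 or more was chosen after seeing the data. edgeR and DESeq2 on recovered reads were not run, since 58.4 to 72% of low values came out whole. No named call or called list reversed, but the largest changes needed a common sign in all lines to be named. Of uncalled list results 8 reversed with the block or equal totals, NOTCH in DE1 and axon guidance in DE2 with both. Of 1787 values of the 199 called gene results under settings other than left-out samples 1739 kept their call and 48 lost it, and of 1917 with a library or line left out 1620 kept it and 297 lost it. Of 12 results named but not called, 12 of 108 values passed under settings and 5 of 108 with samples left out. All 23 called lists lost their call with an estimated correlation, 18 with fry, 2 with equal totals, and 8, 4 and 2 without 7H, 7H1 and 7H2. The block changed no call of a named gene or list other than those given beside the results. The cause was not tested. Depth limits what low genes can show, and the EPI dTAG13 libraries were shallower (17.2 to 21 M reads) than those with DMSO (25.3 to 27.9).

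With the replicate block the counts were 86 in EPI, 362 in PS, 2376 in DE1, 4139 in DE2, and 39, 954 and 2258 for the differences of effects. Fitting only the compared groups gave 2, 11, 2304 and 1564 for EPI to DE2, and 0 and 512 for the first and second difference. A 2-fold rule gave 17 in PS, 631 in DE1, 1241 in DE2, 1646, 3165 and 2423 for the stage steps and 534 for the last difference. Quantile normalisation gave 0 and pseudocount 5 gave 1 for the first difference. Leaving out a library or line gave 3 to 20 in EPI, 8 to 228 in PS, 380 to 950 in DE1 and 998 to 2476 in DE2. The stage steps gave 1349 to 3943, 4736 to 6050 and 3915 to 5340, and the differences 0 to 5, 78 to 323 and 170 to 1022.

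For the differentiation sets the adjusted p with an estimated correlation was 0.355, 0.345, 0.109 and 0.345 for rising genes in EPI to DE2, and 0.423, 0.44 and 0.423 for falling genes in PS to DE2. With fry it was 0.224 and 0.114 for rising genes in EPI and PS, and 0.343, 0.224 and 0.0893 for falling genes in PS to DE2. With lines left out, falling genes ranged from 0.000307 to 0.571 in DE1 and from 8.97e-07 to 0.571 in DE2.

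Genes shared with the replicate block, higher and lower, were 9 and 25 for EPI and PS, 10 and 37 for EPI and DE1, 8 and 35 for EPI and DE2, 72 and 71 for PS and DE1, 74 and 59 for PS and DE2, and 521 and 528 for DE1 and DE2. At an adjusted p under 0.01 the shared lower genes were 0 for EPI and PS, 1 for EPI and DE1, 2 for EPI and DE2, 5 for PS and DE1, 7 for PS and DE2 and 163 for DE1 and DE2. The shared higher genes were 0 for PS and DE1, 0 for PS and DE2 and 104 for DE1 and DE2.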

Other observations

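The tests of zeros were planned before their results were seen, and the gene groups described here were fixed while their members were picked out after the values were seen. Markers of extraembryonic endoderm moved both ways in DE2, where 6 of 23 members rose, 7 fell and 10 were not called (6 rose and 9 fell when adjusted over the list alone), with adjusted p = 0.535. The apolipoprotein genes Apob and Apoe and the basement membrane collagens Col4a1 and Col4a2 were among the rises, and Apoa1 and the endocytic receptor genes Amn and Cubn among the falls. In the HOX list of DE1 2 of 20 members rose, 0 fell and 18 were not called (2 rose and 0 fell when adjusted over the list alone), with a median log2 fold change of 0.84 and adjusted p = 0.0699. The called members were Hoxb9 and Hoxc4.

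In DE2 the proliferation list had 4 rises, Bub1b, Mcm6, Cdc6 and Tyms, among 25 members and 0 falls (4 rose and 0 fell when adjusted over the list alone, adjusted p = 0.2). The cholesterol synthesis list had 3, with Hmgcs1 and Fdps among them, in 21 members and 0 falls (6 rose and 1 fell when adjusted over the list alone, adjusted p = 0.152). In the list of epithelial-mesenchymal transition 3 of 21 members rose, 3 fell and 15 were not called (3 rose and 4 fell when adjusted over the list alone), with adjusted p = 0.874. Cdh2, Mmp14 and Itgb1 rose there, and Vim, Itga5 and Cldn3 fell.

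Exact zeros beside values of at least 50 in the same group occurred in 272 genes, 7 of them called in DE1 and 10 in DE2. Of the 265 in the annotation 27 (10.2%) had exons that overlap another gene on the same strand, against 1238 of 14714 (8.41%), a ratio of 1.21 (Fisher's exact test, p = 0.314). All zeros of a gene lay in 1 cell line for 59 genes (21.7%).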
